A study of Homo sapiens with 16 samples.

How the data were processed

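The series holds 16 samples: 12 mRNA sequencing libraries and 4 chromatin immunoprecipitation libraries with 2 antibodies, whose signal is not analysed here. The 12 mRNA libraries came from MDA-MB-231 cells, per the labels, as monolayer or mammosphere culture, each with control, ZMYND8 knockout and ZMYND8 rescue cells and 2 libraries per group. Monolayers were kept in DMEM with serum and mammospheres in MammoCult medium, RNA was purified with RNeasy columns and DNase, and libraries were made with the KAPA mRNA HyperPrep kit, per the labels' protocols. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

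Reads were converted with bcl2fastq 2.17, checked with FastQC 0.11.2, aligned to hg19 with TopHat and counted with featureCounts, and differential expression was run with edgeR, per the submitters' processing notes. The same notes name Picard 1.127, Bowtie2 2.2.3 and MACS2 2.0.10 for alignment files and chromatin data. The deposited table held 19261 genes by 12 columns, each named FPKM per the file headers, but each column added up to 1000000, so the deposited values are TPM, normalised for gene length and library total by the authors. The table held no fold changes or p-values of the authors, so a planned comparison with them could not be made. It held 26 gene names turned into dates, 2 names present more than once, and 0 mitochondrially encoded genes.

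Whole reads were recovered from the TPM values by finding, for each gene, the relative length at which its values in all libraries became whole numbers of reads, within 0.0001 of a read. This was so for 19261 genes, with a largest distance of 5.79e-05, although the 1852 genes with values in only 1 or 2 libraries leave the length open. The step was tested on simulated data of 1482 genes and recovered 100% of them. Recovered reads came to 15103547 to 19002674 per library. They were used for depth, for the floor of 3 reads per library behind a fold against 0, and for an alternative fit. Intervals and floors of this kind cover counting error only, since the libraries carry no molecular identifiers.

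The main test was limma 3.58.1 in R 4.3.3 (limma-trend) on log2(TPM + 1), for the 14270 genes with at least 1 TPM in at least 2 libraries. A single model with a mean for each of the 6 groups was fitted over the 12 libraries, with 6 residual and 3.38 prior degrees of freedom. Moderated two-sided tests were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were knockout against control, rescue against knockout and rescue against control in each culture, mammosphere against monolayer in control cells, and the difference of the knockout effect between cultures. The difference of the rescue effect between cultures was added after the data were examined. On simulated data for the mammosphere knockout comparison (13639 genes in the fit), log2 changes of 0.25, 0.5, 1 and 2 were called in 36%, 66%, 98% and 100% of genes, with 9 false among 159 calls. For each size, 50 of the better expressed genes were changed, and all other genes were left unchanged. The data gave far more calls (7305), which loosens the adjusted threshold, so these rates do not carry over to them.

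The pairs of libraries differed beyond sampling noise in every group, with a chi-square per degree of freedom of 1.57 to 9.12, highest in monolayer knockout, so they were treated as 2 replicates each. The replicate numbers were tested for pairing across groups by the correlation of library differences, which lay between -0.081 and 0.089 for the 15 pairs of groups. Groups of 2 allow no test for a single outlying library and no test by regrouping the samples. Overlaps of shared, reversed and still different calls were set beside the number from independent lists, and correlations of changes beside 20 simulations of unchanged groups.

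Gene lists were written from general knowledge before the data were examined: 20 lists with 320 entries, of which 298 were found in the table, some under older symbols. Some genes are members of several lists, so calls of such lists are not independent. They covered cholesterol biosynthesis, sterol sensing and uptake, oxysterol and bile acid enzymes, LXR targets, fatty acid synthesis, breast stem cell markers, hypoxia, interferon stimulated genes, cell division, mesenchymal and epithelial markers, amino acid and ER stress, NRF2 targets, cytokines, and ZMYND8 partners. Checks covered leukocyte, endothelial and fibroblast, and luminal markers, histones as a check on poly-A selection, and mitochondrially encoded genes, of which 0 were in the table. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with an estimated correlation and with fry, which tests whether a list moves on balance in a direction. With an estimated correlation camera uses the 6 residual degrees of freedom, far fewer than with the preset one. A call lost there may therefore reflect fewer degrees of freedom as well as correlated genes.

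Named genes were chosen by a rule written before the data were examined: ZMYND8, a fixed set of sterol genes, up to 8 genes with the largest rise and 8 with the largest fall among those called with at least 2 TPM in the higher group and no overlap between groups, and up to 4 called members of each list. The text gives a part of them, and some of the genes are not reported here. Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, median-of-ratios scaling, no variance trend, a replicate block, fits on the libraries of the comparison alone, a minimum log2 change of 1, and leaving out each library. A voom fit on recovered reads, splits of the libraries that overlapping comparisons share, and list tests without genes under 3 reads per library in a group were added after the data were examined. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.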

Results

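Messenger RNA was sequenced from MDA-MB-231 cells, an established human triple-negative breast cancer line, grown either as an attached monolayer or as mammospheres, the floating spheres used to enrich for cells with stem-like properties. Each culture held control cells, cells labelled as knockout of ZMYND8 (a reader of acetylated histones that works with chromatin regulators), and knockout cells labelled as rescued with ZMYND8. Each of the 6 groups had 2 libraries, 12 in all, and each library held between 15103547 and 19002674 reads over 19261 genes. Values below are group means ± SD (n = 2) in TPM, a transcript abundance scaled to a total of 1000000 per library, and changes are log2 differences on the scale of log2(TPM + 1). The study's title names the metabolism of 27-hydroxycholesterol, an oxysterol that CYP27A1 makes from cholesterol and CYP7B1 breaks down.

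ZMYND8 mRNA was not lower in the libraries labelled knockout in either culture. In monolayer it stood at 163 ± 4.1 TPM in control, 172 ± 9.9 in knockout and 454 ± 2.5 in rescue libraries. In mammospheres it stood at 131 ± 3.7, 201 ± 3.7 and 563 ± 17. Single libraries read 160 and 166 TPM in monolayer control, 179 and 165 in monolayer knockout, 456 and 453 in monolayer rescue, 129 and 134 in mammosphere control, 204 and 199 in mammosphere knockout, and 574 and 551 in mammosphere rescue. The knockout difference was 0.07 in monolayer (SE 0.045, limma adjusted p = 0.218) and 0.61 in mammospheres (SE 0.045, adjusted p = 5.15e-06), and the difference between the cultures was itself 0.54 (adjusted p = 0.000323). Without monolayer knockout replicate 2 the monolayer difference was 0.13, with an adjusted p of 0.0347. ZMYND8 rose by 1.40 from knockout to rescue in monolayer (adjusted p = 9.15e-09) and by 1.48 in mammospheres (adjusted p = 1.95e-08). A gene-level value holds no information on an edited site, so the knockout is named by its label throughout.

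**Figure D1:**
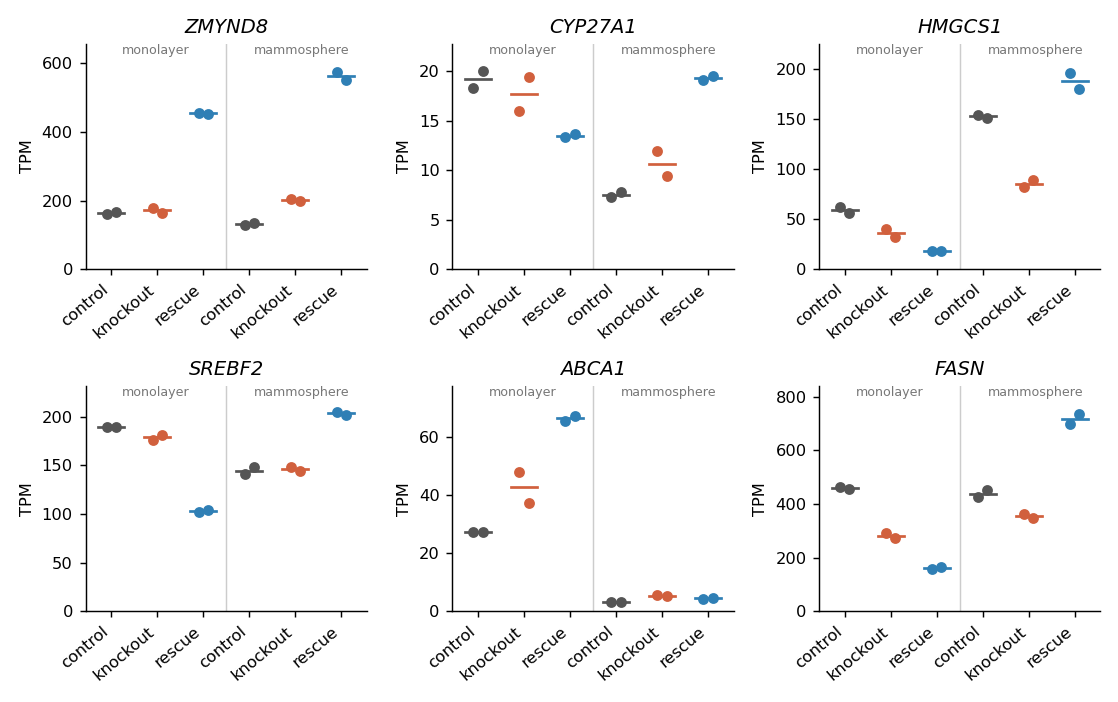
TPM of ZMYND8, CYP27A1, HMGCS1, SREBF2, ABCA1 and FASN in the 12 libraries (points) with the mean of each group (line), for monolayer on the left and mammospheres on the right of each panel. ZMYND8 lies between 129 and 204 TPM in all control and knockout libraries and between 453 and 574 in the rescue libraries.

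In mammospheres, 13 of 21 cholesterol biosynthesis genes were lower and 1 higher in the libraries labelled knockout than in control, a list call that did not hold with an estimated correlation (camera adjusted p = 0.367). HMGCS1, an early enzyme of the pathway, fell from 153 ± 2.7 to 85.3 ± 4.7 TPM. IDI1 fell from 190 ± 15 to 118 ± 9.1, and SC5DL (now SC5D), a late step of the pathway, from 30.5 ± 2.5 to 19.1 ± 0.74. ABCA1, which exports cholesterol, rose from 3.13 ± 0.085 to 5.4 ± 0.25 TPM. The apolipoprotein gene APOC1 fell from 41.6 ± 1.3 to 15.9 ± 1.5 TPM, and APOE fell by 1.14 on the log2 scale.

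CYP27A1 rose from 7.52 ± 0.35 to 10.7 ± 1.8 TPM with the knockout label in mammospheres, a change of 0.45 (SE 0.12, limma adjusted p = 0.0112). Its call was lost without mammosphere control replicate 1 (0.40, adjusted p = 0.0658) and without mammosphere knockout replicate 1 (0.29, adjusted p = 0.0956). CYP7B1 had 1 read in each mammosphere control library, 2 and 3 reads in the monolayer control libraries, and 0 reads in the other 8, so it was not tested and a difference was not detectable at this depth. SREBF2, the transcription factor behind sterol synthesis, did not pass the test at 145 ± 5.3 and 146 ± 3.0 TPM (0.02, adjusted p = 0.730), and its sign changed without mammosphere control replicate 1 (-0.02) or mammosphere knockout replicate 1 (-0.004). ABCG1, another exporter, stood at 0.0583 ± 0.082 and 0.0242 ± 0.034 TPM, with at most 3 reads per library.

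Among the largest changes in mammospheres, MMP2, a matrix-degrading protease, rose from 1.34 ± 0.19 to 57.3 ± 0.92 TPM. LGR6, a stem cell receptor, rose from 0.914 ± 0.29 to 47.4 ± 2.0, KISS1, which encodes metastasis-related kisspeptins, from 4.49 ± 0.58 to 180 ± 14, and SIGLEC15, a sialic acid receptor, from 0.262 ± 0.24 to 56.2 ± 4.8. The leukotriene pathway gene ALOX5AP rose from 3.48 ± 1.0 to 60.6 ± 4.1, and the adhesion receptor gene GPR110 from 0.472 ± 0.077 to 15.0 ± 1.8. The metallothionein gene MT1A fell from 38.9 ± 4.1 to 0.22 ± 0.31 TPM, the myosin genes MYH10 and MYO5C from 30.8 ± 0.93 to 0.474 ± 0.06 and from 39.5 ± 0.03 to 1.01 ± 0.19, and the hexosamine enzyme gene GFPT2 from 76.1 ± 0.87 to 2.85 ± 0.064. The secreted trefoil peptides TFF2 and TFF3 fell from 16.3 ± 1.2 to 0 reads and from 18.2 ± 1.4 to 0.276 ± 0.39 TPM. SPANXD and SPANXE were also among the genes with the largest rise, but as near-identical copies whose reads may have been shared they remain uncertain.

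By limma, 7305 of 14270 genes tested differed in mammospheres at an adjusted p under 0.05, 3077 higher and 4228 lower in the libraries labelled knockout. The share of calls that were higher was 42.1%, and 47.9% after median-of-ratios scaling and 47.6% by voom, so most of the excess of falls depends on the scaling. Of these 7305, 772 had a log2 change of at least 1 on the scale of log2(TPM + 1), 366 higher and 406 lower. Genes at low TPM can change by over 2-fold without reaching that value. Among the 23 genes of cell division, 22 were lower and 0 higher, with TOP2A down from 285 ± 17 to 152 ± 10 and RRM2 from 224 ± 6.3 to 124 ± 3.7 TPM (camera adjusted p = 1.75e-07; adjusted p = 0.188 with an estimated correlation). Cholesterol biosynthesis had 13 lower and 1 higher of 21 (camera adjusted p = 0.00912; adjusted p = 0.367 with an estimated correlation), and fatty acid synthesis 7 lower and 1 higher of 14, led by ME1 (camera adjusted p = 0.0404; adjusted p = 0.238 with an estimated correlation). Interferon stimulated genes had 14 higher and 3 lower of 21, with OAS1 and OAS2 higher by 2.11 and 1.17 and IFI27 lower by a log2 change of -2.11 (camera adjusted p = 0.000522; adjusted p = 0.188 with an estimated correlation). Mesenchymal markers had 8 higher and 1 lower of 13, including TGFBI, from 23.8 ± 0.51 to 161 ± 7.2, and SPARC, from 0.696 ± 0.1 to 9.7 ± 0.46 TPM (camera adjusted p = 5.88e-05; adjusted p = 0.188 with an estimated correlation). Epithelial markers had 7 lower and 0 higher of 12, with CLDN4 at -1.68 and EPCAM at -1.43 (camera adjusted p = 0.0305; adjusted p = 0.236 with an estimated correlation).

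Luminal breast markers, taken as markers of other cell lines, had 5 lower and 2 higher of 8 in mammospheres, with AGR2 at -3.25 (camera adjusted p = 0.0357; adjusted p = 0.188 with an estimated correlation). Endothelial and fibroblast markers, taken as markers of other cells, had 5 higher and 0 lower of 6 (camera adjusted p = 0.00912; adjusted p = 0.188 with an estimated correlation), led by the matrix genes DCN and COL1A1, which are not specific to those cells. Adjusted over the list alone, each of the 8 lists named for this comparison gave the same counts. No camera call of this comparison held with an estimated correlation.

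In monolayer, the libraries labelled knockout had less cytokine mRNA than control. The lists of cholesterol and fatty acid synthesis were also called lower, but not with an estimated correlation (camera adjusted p = 0.418 and 0.108). IL1B fell from 513 ± 8.8 to 72.8 ± 4.0 TPM, the chemokine CCL2 from 22 ± 0.33 to 0.455 ± 0.019, and the growth factor CSF2 from 210 ± 9.1 to 45.3 ± 0.86. HMGCS1 fell from 59.4 ± 4.1 to 36.0 ± 5.3, MVD from 81.3 ± 0.14 to 47.2 ± 0.6, and FASN, the fatty acid synthase, from 460 ± 3.9 to 282 ± 11 TPM. ABCA1 rose from 27.3 ± 0.1 to 42.7 ± 7.8 TPM, while ABCG1 fell from 1.88 ± 0.58 to 0.0943 ± 0.004, with 2 reads in each knockout library.

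CYP27A1 stood at 19.2 ± 1.2 in control and 17.7 ± 2.4 TPM in knockout monolayers, a difference of -0.12 that did not pass the test (limma adjusted p = 0.460) and was 0.02 without monolayer knockout replicate 1, and SREBF2 at 190 ± 0.14 and 179 ± 3.8 (-0.09, adjusted p = 0.0841). The gain of MMP2, SIGLEC15, LGR6 and GPR110 was also seen in monolayer, with changes of 5.54, 4.74, 4.74 and 4.23. MMP2 reached 184 ± 6.6 TPM from 2.99 ± 0.39. The trefoil peptides were abundant in control monolayers and nearly lost with the knockout label: TFF2 fell from 429 ± 0.37 to 1.08 ± 0.12 TPM, TFF1 from 122 ± 7.1 to 0 reads (at least 118-fold lower, against a floor of 3 reads in each library), and TFF3 from 86.0 ± 5.6 to 0.332 ± 0.47. The translation factor gene EEF1A2 fell from 51.4 ± 3.1 to 0.0411 ± 0.058, the protease gene TMPRSS3 from 53.7 ± 0.47 to 0.121 ± 0.029, and the collagen gene COL6A2 from 88.8 ± 3.4 to 1.19 ± 0.14 TPM.

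By limma, 6700 genes differed in monolayer, 3584 higher and 3116 lower in the libraries labelled knockout. Of these, 881 had a log2 change of at least 1, 298 higher and 583 lower. The share of calls that were higher was 53.5%, but 49.75% after median-of-ratios scaling, 48.7% by voom and 48.25% without monolayer knockout replicate 1, so the side with more calls is not settled. The monolayer knockout pair was the most spread of the 6 pairs, with a median SD of 0.0786 (log2) over genes at 10 TPM or more, against 0.037 to 0.0504 in the other pairs. The model gave each gene a single variance for all 6 groups, so p-values of comparisons with this pair may be too small. Inflammatory cytokines had 14 lower and 1 higher of 16 (camera adjusted p = 1.94e-08; adjusted p = 0.046 with an estimated correlation), and luminal breast markers 7 lower and 1 higher of 8 (camera adjusted p = 0.000169; adjusted p = 0.046 with an estimated correlation). Those 2 calls held with an estimated correlation and the other 8 of this comparison did not. Genes of cell division had 20 higher and 0 lower of 23, with MKI67 up from 74.3 ± 0.71 to 116 ± 19 and PCNA from 166 ± 2.0 to 236 ± 10 TPM (camera adjusted p = 6.28e-06; adjusted p = 0.160 with an estimated correlation). Adjusted over the list alone, 21 were higher and 1 lower.

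Among the lipid lists in monolayer, fatty acid synthesis had 10 lower and 1 higher of 14, ME1 among them (camera adjusted p = 0.000888; adjusted p = 0.108 with an estimated correlation), and 11 lower and 1 higher adjusted over the list alone. Cholesterol biosynthesis had 12 lower and 5 higher of 21 (camera adjusted p = 0.0255; adjusted p = 0.418 with an estimated correlation). Sterol sensing and uptake had 7 lower and 3 higher of 15, with NPC1 at -0.66 (camera adjusted p = 0.017; adjusted p = 0.108 with an estimated correlation). Targets of the oxysterol receptor LXR had 8 lower and 3 higher of 14, with APOE at -1.89 and APOC1 at -1.74 (camera adjusted p = 0.0216; adjusted p = 0.108 with an estimated correlation). Breast stem cell markers had 9 lower and 4 higher of 16, led by LGR5 at -1.97 and ABCG2 at -1.60 (camera adjusted p = 0.0205; adjusted p = 0.108 with an estimated correlation).

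Partner proteins of ZMYND8 had 11 higher and 1 lower of 19 in monolayer, HDAC1 and CHD4 among the higher (camera adjusted p = 0.0205; adjusted p = 0.350 with an estimated correlation). Epithelial markers had 7 lower and 2 higher of 12, with ELF3 at -2.17 and CDH1 at -1.19 (camera adjusted p = 0.0117; adjusted p = 0.133 with an estimated correlation), and 8 lower and 2 higher adjusted over the list alone. The counts of the other lists called in monolayer were the same adjusted over the list alone. Mesenchymal markers in monolayer had a median of -0.10 and a mean of 0.48, and MMP9 fell from 19.2 ± 2.1 to 0.432 ± 0.19 TPM. Their camera test pointed upward without a call (adjusted p = 0.384).

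The knockout label moved many of the same genes in both cultures. MMP2, SIGLEC15, LGR6 and GPR110 were higher, and TFF2, TFF3, HMGCS1, ME1, APOE and ABCG2 lower, in both. Across genes, which are not independent replicates, the changes of the 2 cultures had a Pearson's r of 0.625 and a Spearman's rho of 0.508, with a covariance of 0.202 against 0.0004 in simulated unchanged groups. Of the calls, 1753 genes were higher and 1889 lower in both, against 772.8 and 923.2 for independent lists (one-sided Fisher's exact test across genes, p at the smallest value written, 1e-300, for each). Another 670 genes were called in opposite directions.

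The size of the knockout difference depended on the culture for 4535 genes by limma's test of the difference, 1867 more positive and 2668 more negative in mammospheres, a split that became even after rescaling (41.2% positive as deposited, 51.7% after median-of-ratios scaling). Among the 517 differences of at least 1 on the log2 scale the split ran the other way, with 377 more positive and 140 more negative. Genes of cell division moved apart together: 23 of 23 were more negative in mammospheres, with MKI67 and PCNA higher in monolayer and TOP2A and RRM2 lower in mammospheres (camera adjusted p = 1.18e-14; adjusted p = 0.0936 with an estimated correlation). Inflammatory cytokines, 14 of 16 lower in monolayer, had 3 lower and 6 higher in mammospheres, and 14 differed upward between the cultures (camera adjusted p = 5.07e-12; adjusted p = 0.0392 with an estimated correlation, and 0.0512 without genes that lay under 3 reads per library in a group, CCL2 among them). IL1B, for example, fell by 2.80 in monolayer and by 1.17 in mammospheres, where its control level was 26.5 ± 1.1 TPM.

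**Figure D2:**
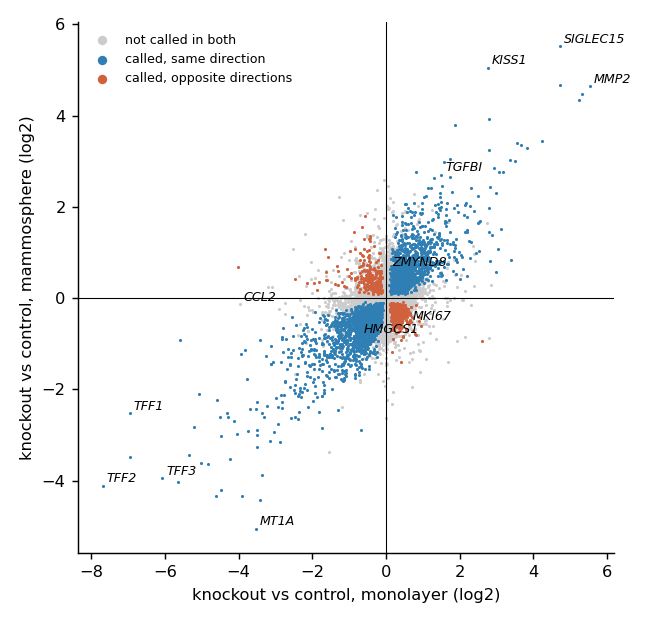
Log2 change of the 14270 genes tested between knockout and control in monolayer (horizontal) and in mammospheres (vertical), each point a gene, coloured by whether limma called it in both cultures. Pearson's r across genes is 0.625, and 670 of the genes called in both cultures moved in opposite directions.

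In mammospheres, mRNAs of cholesterol biosynthesis were higher in rescue than in knockout libraries, although the list's call did not hold with an estimated correlation (camera adjusted p = 0.117). HMGCS1 rose from 85.3 ± 4.7 in knockout to 188 ± 11 TPM in rescue libraries, and SREBF2 from 146 ± 3.0 to 203 ± 2.5. SQLE, LSS, IDI1 and SC5DL, later enzymes of the pathway, rose by 1.21, 1.25, 1.22 and 1.54. CYP27A1 rose from 10.7 ± 1.8 to 19.3 ± 0.3 TPM (0.81, limma adjusted p = 0.000316). ABCA1 went from 5.4 ± 0.25 to 4.48 ± 0.37, which did not pass the test (-0.23, adjusted p = 0.111), but passed it after median-of-ratios scaling (-0.34, adjusted p = 0.0152). ABCG1 was at 0 reads in both rescue libraries.

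Part of the knockout-label changes were undone in mammosphere rescue libraries. GFPT2 returned to 72.5 ± 4.6 TPM from 2.85 ± 0.064, and KISS1 and SIGLEC15 fell to 21.8 ± 0.11 from 180 ± 14 and to 8.67 ± 2.2 from 56.2 ± 4.8, still above control. Some genes passed beyond control. TFF3 reached 44.7 ± 0.24 TPM from 0.276 ± 0.39, against 18.2 ± 1.4 in control, OLFML3, an olfactomedin, reached 318 ± 12 TPM against 9.73 ± 0.76 in control, the protease CAPN8 reached 40.5 ± 4.8 against 2.1 ± 0.52, and the collagenase MMP1 406 ± 48 against 107 ± 2.4. The matrix genes TGFBI and SPARC fell from 161 ± 7.2 to 15.7 ± 1.1 and from 9.7 ± 0.46 to 0.216 ± 0.042, below the 23.8 ± 0.51 and 0.696 ± 0.1 TPM of control. ALOX5AP, the mucosal protein gene DMBT1, GPR110 and the blood-cell adaptor gene HCLS1 changed by -4.47, -3.71, -3.37 and -4.04, and SUSD2 and the trypsin inhibitor gene SPINK1 rose by 4.32 and 4.13.

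By limma, 8043 genes differed between rescue and knockout mammospheres, 5287 higher and 2756 lower. Of these, 971 had a log2 change of at least 1, 664 higher and 307 lower. The median change over all genes was 0.115 as deposited and 0 after median-of-ratios scaling, and the share of calls that were higher went from 65.7% to 49.8%, so small rises here depend on the scaling. Cholesterol biosynthesis had 20 higher and 0 lower of 21, with a median of 1.01 (camera adjusted p = 2.49e-09; adjusted p = 0.117 with an estimated correlation). Fatty acid synthesis had 10 higher and 1 lower of 14, with ACSS2 at 1.68 and FASN at 1.02 among the higher (camera adjusted p = 0.00904; adjusted p = 0.162 with an estimated correlation), and 11 higher adjusted over the list alone. Genes of cell division had 17 lower and 1 higher of 23, with TYMS at -0.94 and AURKB at -0.64 (camera adjusted p = 2.54e-06; adjusted p = 0.162 with an estimated correlation). Mesenchymal markers had 8 lower and 0 higher of 13 (camera adjusted p = 4.3e-07; adjusted p = 0.1 with an estimated correlation), with 9 lower adjusted over the list alone.

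Targets of the oxidative stress factor NRF2 had 8 higher and 0 lower of 10 in rescued mammospheres, with ABCC2 at 1.86 and HMOX1 at 1.23 (camera adjusted p = 0.00216; adjusted p = 0.1 with an estimated correlation), and 9 higher adjusted over the list alone. Replication-dependent histone genes, kept as a check on poly-A selection, had 8 higher and 1 lower of 11, HIST1H2BJ and HIST1H4H among them (camera adjusted p = 0.0315; adjusted p = 0.162 with an estimated correlation), and 9 higher and 2 lower adjusted over the list alone. Their median change with rescue was 1.00 in mammospheres and 0.78 in monolayer. Whether the rescue libraries differed in their preparation was not tested, so such a difference stays open for the comparisons with rescue. Leukocyte markers had 3 lower of 6, CSF1R at -2.25 (camera adjusted p = 0.00936; adjusted p = 0.162 with an estimated correlation), and endothelial and fibroblast markers 3 lower of 6 (camera adjusted p = 0.0315; adjusted p = 0.162 with an estimated correlation). No camera call of this comparison held with an estimated correlation.

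With rescue in monolayer, HMGCS1 fell from 36.0 ± 5.3 to 18.2 ± 0.032 TPM and SREBF2 from 179 ± 3.8 to 103 ± 1.3. The desaturases FADS2 and SCD fell from 874 ± 39 to 268 ± 0.53 and from 1310 ± 34 to 484 ± 0.18, and the LXR gene NR1H3 from 37.2 ± 0.023 to 7.41 ± 0.04 TPM. ABCA1 rose from 42.7 ± 7.8 to 66.6 ± 1.1, and ABCG1 stayed near the floor at 0.0923 ± 0.065 TPM. CYP27A1 fell from 17.7 ± 2.4 to 13.5 ± 0.23 TPM (-0.36, limma adjusted p = 0.0222), a call lost without monolayer knockout replicate 2 (-0.23, adjusted p = 0.151), without monolayer rescue replicate 1 (-0.35, adjusted p = 0.0880) and without monolayer rescue replicate 2 (-0.38, adjusted p = 0.0653).

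Rescued monolayers also lost hypoxia genes and gained stress genes. The carbonic anhydrases CA9 and CA12 fell from 44.6 ± 1.8 to 0.215 ± 0.15 and from 69.2 ± 0.74 to 8.05 ± 0.37 TPM, and NDRG1 from 1500 ± 40 to 210 ± 1.9. The amino acid and ER stress genes CHAC1, TRIB3, PSAT1 and DDIT3 rose by 2.29, 1.89, 1.83 and 1.74, PSAT1 to 777 ± 12 TPM. MMP1 rose from 10.8 ± 0.71 to 911 ± 24, the urea cycle enzyme gene ASS1 from 26.5 ± 1.9 to 726 ± 24, and S100P from 8.69 ± 1.3 to 239 ± 1.1. SPINK1 rose from 0 reads to 52.9 ± 2.9 TPM (at least 45.7-fold higher, against the floor of 3 reads in each library), SUSD2 by 5.4 and the protease inhibitor gene SLPI by 4.62. SPARC, DMBT1, GPR110, CD96 and TGFBI changed by -5.77, -5.21, -5.88, -4.88 and -3.99. Of the trefoil peptides, TFF2 rose to 18.9 ± 1.1, TFF3 to 7.19 ± 1.4 and TFF1 to 1.86 ± 0.23 TPM, all below control.

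By limma, 9426 genes differed between rescue and knockout monolayers, 5170 higher and 4256 lower. Of these, 1932 had a log2 change of at least 1, 967 higher and 965 lower. The share of calls that were higher fell from 54.85% to 48.9% after median-of-ratios scaling and was 49.1% by voom. Hypoxia genes had 18 lower and 3 higher of 25 (camera adjusted p = 6.57e-06; adjusted p = 0.017 with an estimated correlation) and amino acid and ER stress genes 14 higher and 0 lower of 15 (camera adjusted p = 4.39e-06; adjusted p = 0.017 with an estimated correlation). Those 2 calls held with an estimated correlation and the other 11 did not. Cholesterol biosynthesis had 16 lower and 3 higher of 21, led by TM7SF2 at -1.80, MSMO1 at -1.66 and FDFT1 at -1.34 (camera adjusted p = 4.31e-05; adjusted p = 0.125 with an estimated correlation). Sterol sensing and uptake had 11 lower and 2 higher of 15, with INSIG1 at -1.26 (camera adjusted p = 0.00454; adjusted p = 0.0983 with an estimated correlation). Fatty acid synthesis had 11 lower and 3 higher of 14 (camera adjusted p = 0.00271; adjusted p = 0.0983 with an estimated correlation), LXR targets 9 lower and 2 higher of 14 (camera adjusted p = 0.00767; adjusted p = 0.0983 with an estimated correlation), and oxysterol and bile acid enzymes 5 lower and 1 higher of 8, with ACOX2 at -1.56 (camera adjusted p = 0.0392; adjusted p = 0.125 with an estimated correlation).

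Interferon stimulated genes in rescued monolayers had 15 higher and 3 lower of 21, with MX1 up from 2.81 ± 0.15 to 24.3 ± 0.032 and OAS3 from 13.9 ± 1.4 to 60.1 ± 0.8 TPM (camera adjusted p = 0.00271; adjusted p = 0.129 with an estimated correlation). Cytokines had 13 higher and 3 lower of 16, with IL6 up from 22.5 ± 0.055 to 131 ± 3.1 and IL1A from 1.56 ± 0.26 to 11.4 ± 0.26 TPM (camera adjusted p = 0.0104; adjusted p = 0.131 with an estimated correlation). NRF2 targets had 8 higher and 1 lower of 10, HMOX1 at 0.88 (camera adjusted p = 0.0225; adjusted p = 0.125 with an estimated correlation), and histone genes 9 higher and 0 lower of 11 (camera adjusted p = 0.00805; adjusted p = 0.125 with an estimated correlation). Mesenchymal markers had 9 lower and 2 higher of 13 (camera adjusted p = 0.00328; adjusted p = 0.125 with an estimated correlation), and leukocyte markers 4 lower and 0 higher of 6 (camera adjusted p = 0.0104; adjusted p = 0.129 with an estimated correlation). Adjusted over the list alone, the 13 lists called in rescued monolayers gave the same counts.

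**Figure D3:**
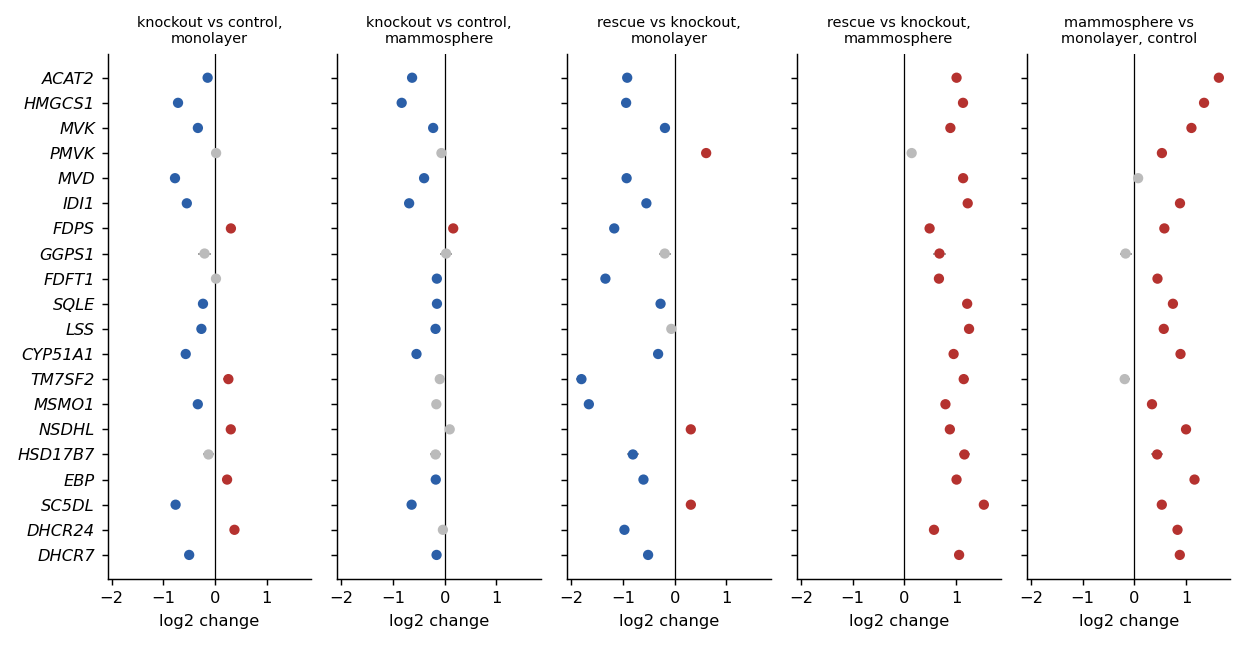
Log2 change of 20 of the 21 cholesterol biosynthesis genes in 5 comparisons, with bars for the SE and colour for limma calls (red higher, blue lower, grey not called). With rescue, 20 of the 21 were higher in mammospheres and 16 lower in monolayer.

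The rescue libraries did not return to the control profile in either culture. Cholesterol biosynthesis mRNAs in rescued mammospheres stood above control, with 20 of 21 genes higher (camera adjusted p = 1.35e-06; adjusted p = 0.374 with an estimated correlation), and in rescued monolayers below it, with 19 lower and 2 higher (camera adjusted p = 1.55e-06; adjusted p = 0.0838 with an estimated correlation). Genes of cell division in rescued mammospheres stood below control, with 22 of 23 lower (camera adjusted p = 2.29e-10; adjusted p = 0.374 with an estimated correlation). The histone genes kept as a check on poly-A selection stood above control by a median of 1.25 in rescued mammospheres, where camera did not call them. In rescued monolayers their median was 1.01 above control. In rescued monolayers 13 lists differed from control, and 5 held with an estimated correlation, at a camera adjusted p of 0.0317 each. These were sterol sensing, LXR targets, fatty acid synthesis, hypoxia genes, and amino acid and ER stress genes. The LXR list shares SREBF1 and MYLIP with sterol sensing and SCD and FASN with fatty acid synthesis, so those calls are not independent. Its member ABCA1 went the other way, at 66.6 TPM in rescued and 27.3 in control monolayers. MYH10, MYO5C, EEF1A2 and MT1A stayed low in rescue libraries of both cultures, with MYO5C at 0.502 ± 0.036 TPM in monolayer and 0.872 ± 0.021 in mammospheres. By limma, 9237 genes differed between rescue and control in mammospheres (5258 higher, 3979 lower) and 9915 in monolayer (5485 higher, 4430 lower). After median-of-ratios scaling the higher share of these calls went from 56.9% to 49.0% in mammospheres and from 55.3% to 48.3% in monolayer.

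Of the genes called with the knockout label, 2645 in mammospheres (36.2%) and 3081 in monolayer (46.0%) were called the opposite way with rescue. MMP2, GPR110 and SIGLEC15 were among the reversed rises, and TFF2 and TFF3 among the reversed falls, in both cultures. Without mammosphere knockout replicate 1 the mammosphere count was 1740. Reversed rises numbered 896 in mammospheres against 594.3 for independent lists, and reversed falls 1749 against 1566.5. In monolayer they numbered 1679 against 1068.9 and 1402 against 1128.9. The comparisons share the knockout libraries, so simulated unchanged groups gave an r of -0.499 and a covariance of -0.0183 in mammospheres, beside an observed r of -0.250 and a covariance of -0.0783. In monolayer the simulated values were -0.492 and -0.0181, and the observed ones -0.297 and -0.136. With the knockout libraries split, so that each served in a single comparison, the reversed calls numbered 1858 and 1854 in mammospheres (against 1522.2 and 1426.9 for independent lists) and 2679 and 2829 in monolayer (against 2045 and 2034.9), for the 2 ways of splitting. Pearson's r across genes was then -0.179 and -0.186 in mammospheres and -0.217 and -0.253 in monolayer.

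Among genes called with the knockout label, 4767 in mammospheres (65.3%) and 3860 in monolayer (57.6%) still differed from control in the same direction in the rescue libraries. Of the log2 changes of at least 1, 581 of 772 and 607 of 881 still differed in this way. LGR6 in mammospheres is an example of them, at 0.914 ± 0.29 TPM in control, 47.4 ± 2.0 in knockout and 30.7 ± 1.3 in rescue libraries. The counts of calls that still differed overlap with the reversed calls, since a gene reversed in part counts in both. Of the reversed calls, 1273 in mammospheres and 1180 in monolayer no longer differed from control, and 861 and 1401 passed beyond it. Another 1984 and 1805 knockout calls moved further from control with rescue. No number from independent lists was set beside these 2 counts, so they are not read as an excess. The knockout and rescue libraries are compared here with the same control libraries, for which simulated unchanged groups gave a covariance of 0.0183 in mammospheres and 0.0189 in monolayer, beside 0.216 and 0.220 observed. With the control libraries split, so that each served in a single comparison, 3758 and 3672 calls in mammospheres (against 1747.8 and 1594.9 for independent lists) and 2930 and 2911 in monolayer (against 1658.1 and 1624.5) still differed.

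Among the largest differences between control cultures, the cystatins CST1 and CST4, secreted protease inhibitors, fell from 8060 ± 250 TPM in monolayer to 58.3 ± 1.0 in mammospheres and from 2900 ± 90 to 60.1 ± 0.059. CSF2, IL1B and IL8 (CXCL8) changed by -4.64, -4.22 and -3.61, CCL2 was left with 1 read in each mammosphere library, and the cytokine gene TNFSF15 from 84.7 ± 2.3 to 0.742 ± 0.034. The trefoil peptides TFF1 and TFF2 fell from 122 ± 7.1 to 4.75 ± 0.27 and from 429 ± 0.37 to 16.3 ± 1.2. The lipoxygenase gene ALOX15B rose from 0.145 ± 0.038 to 44.9 ± 2.8, FKBP5, a chaperone of steroid receptors, from 6.69 ± 0.59 to 164 ± 5.4, RGS2 from 8.86 ± 0.28 to 169 ± 4.3, and the matrix proteoglycan DCN from 0.0311 ± 0.044 to 13.6 ± 0.97 TPM. SLPI rose by 3.31.

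Cholesterol biosynthesis genes were higher in control mammospheres than in control monolayers, while the cholesterol exporter genes ABCA1 and ABCG1 were lower. The call of the list did not hold with an estimated correlation (camera adjusted p = 0.0944). HMGCS1 stood at 153 ± 2.7 against 59.4 ± 4.1 TPM, with ACAT2 and EBP higher by 1.64 and 1.16. ABCA1 fell from 27.3 ± 0.1 to 3.13 ± 0.085, APOE from 17.3 ± 0.38 to 3.72 ± 0.56, and CYP27A1 from 19.2 ± 1.2 to 7.52 ± 0.35 TPM (-1.24, limma adjusted p = 8.99e-06). ABCG1 fell from 1.88 ± 0.58 to 0.0583 ± 0.082, SREBF2 from 190 ± 0.14 to 145 ± 5.3, SREBF1 by 1.55, and ZMYND8 by 0.31 (adjusted p = 0.000173). RRM2, which makes the building blocks of DNA, rose from 38.9 ± 3.5 to 224 ± 6.3, and the cyclin CCNE2 from 5.3 ± 1.2 to 24.6 ± 2.7 TPM.

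By limma, 9659 genes differed between the control cultures, 4571 higher and 5088 lower in mammospheres. Of these, 2203 had a log2 change of at least 1, 816 higher and 1387 lower. Genes of cell division had 23 higher of 23 (camera adjusted p = 4.71e-12; adjusted p = 0.0534 with an estimated correlation), and cholesterol biosynthesis 18 higher and 0 lower of 21 (camera adjusted p = 9.73e-07; adjusted p = 0.0944 with an estimated correlation). Hypoxia genes had 22 lower and 1 higher of 25, with CA9 at -2.78, NDRG1 at -2.59 and ANGPTL4 at 2.81 (camera adjusted p = 7.55e-07; adjusted p = 0.0227 with an estimated correlation). Cytokines had 14 lower and 0 higher of 16 (camera adjusted p = 2.96e-06; adjusted p = 0.0487 with an estimated correlation), and amino acid and ER stress genes 14 lower and 1 higher of 15, with CHAC1 at -2.33 and ASNS at -1.87 (camera adjusted p = 1.58e-05; adjusted p = 0.0253 with an estimated correlation).

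LXR targets had 10 lower and 0 higher of 14 in control mammospheres, MYLIP at -1.62 (camera adjusted p = 0.0015; adjusted p = 0.0487 with an estimated correlation), sterol sensing and uptake 12 lower and 2 higher of 15 (camera adjusted p = 0.00153; adjusted p = 0.0487 with an estimated correlation), and luminal markers 7 lower and 1 higher of 8 (camera adjusted p = 0.00284; adjusted p = 0.0487 with an estimated correlation). Interferon stimulated genes had 13 lower and 3 higher of 21, IFI27 and IFI6 among the lower (camera adjusted p = 0.0418; adjusted p = 0.287 with an estimated correlation). Of the 9 calls, the 6 for hypoxia, cytokines, stress, LXR targets, sterol sensing and luminal markers held with an estimated correlation. Adjusted over the list alone, the 9 lists called between control cultures gave the same counts. Medium and attachment changed together between the cultures, and neither was varied alone.

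**Figure D4:**
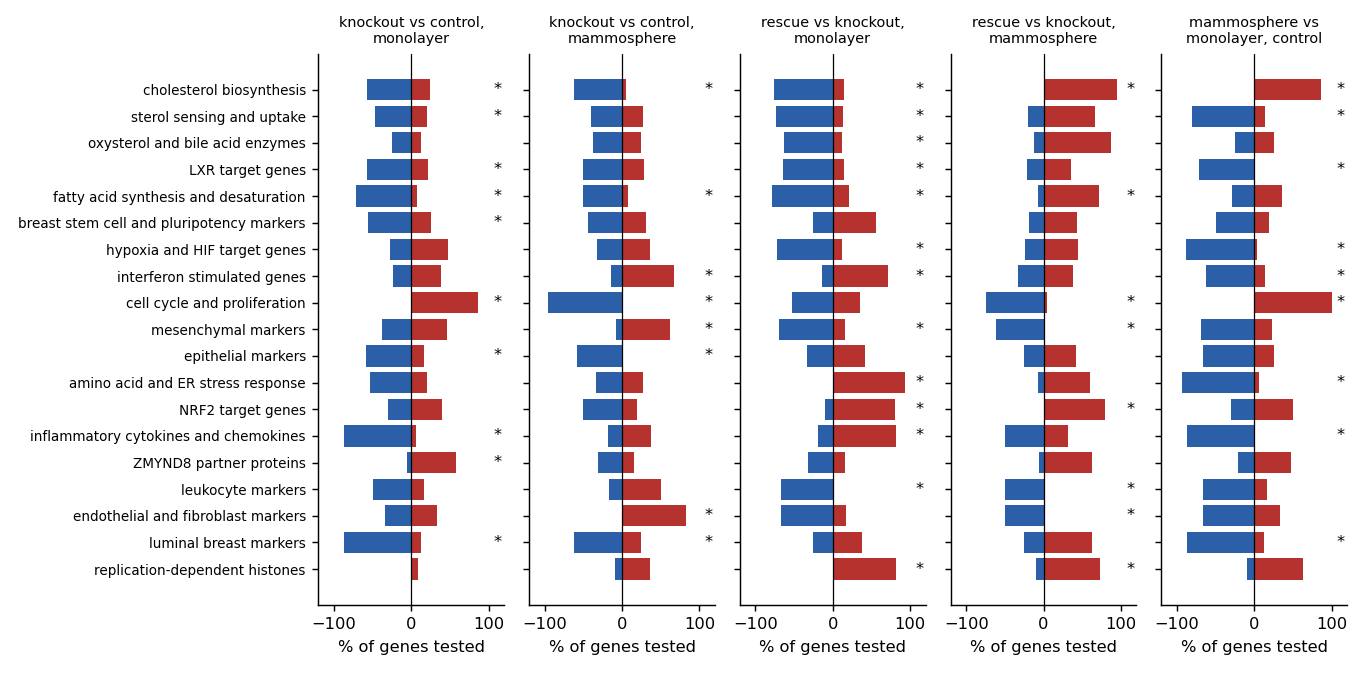
Share of each list's tested genes that limma called higher (red, to the right) and lower (blue, to the left) in 5 comparisons, in percent, with a star where camera with its preset correlation gave an adjusted p under 0.05. Genes of cell division were 22 of 23 lower with the knockout label in mammospheres and 20 of 23 higher in monolayer.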

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

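The difference of the rescue effect between cultures, and the tests on ZMYND8 mRNA, on knockout differences kept with rescue, on split control libraries and on genes under 3 reads per library, were chosen only after the results were seen. The tests on scaling, gene length and single libraries were set down before their results were seen.

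ZMYND8 mRNA was not lower in the libraries labelled knockout in either culture. Control and knockout labels exchanged in a single culture would give opposite knockout changes in the 2 cultures, but Pearson's r between them was 0.625, which argues against such an exchange. Labels exchanged in both cultures, with an edit that lowers the mRNA, would put ZMYND8 well above control in the libraries labelled knockout of both cultures, by at least 1 on the log2 scale. The changes were 0.61 in mammospheres and 0.07 in monolayer (SE 0.045), which argues against it. An edit that leaves the transcript in place could give such values with labels as given or exchanged in both cultures. These last explanations cannot be told apart, because gene-level values hold no reads over the edited site and no measure of the protein. The knockout change of ZMYND8 was larger in mammospheres than in monolayer by 0.54 (limma adjusted p = 0.000323), and no biological explanation of that difference was tested.

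Cholesterol biosynthesis genes rose with rescue in mammospheres and most fell with it in monolayer, so that the rescue effect differed between cultures by a median of 1.57 over the 21 genes (camera adjusted p = 2.97e-10; adjusted p = 0.0710 with an estimated correlation). Scaling of the libraries could shift a whole list, but after median-of-ratios scaling the median was 1.51. A trend on gene length was removed over all genes tested and the median was 1.53. A single unusual library could also carry the difference, but over the 8 fits that each left out a library the lowest median was 1.54 and the highest 1.62. These values argue against the 3 technical explanations as the whole cause, while the culture conditions and the state of the cells at harvest stay open and untested.

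Many knockout differences from control were also present in the rescue libraries. Too little total ZMYND8 mRNA in the rescue libraries is argued against by its level, which lay above control by 1.47 in monolayer and by 2.09 in mammospheres. That total may include the transcript already present in the knockout libraries, at 172 TPM in monolayer and 201 in mammospheres. The share from the re-expressed gene is therefore not known, and protein was not measured. Differences between the cell lines that do not depend on ZMYND8 could leave the same genes changed in knockout and rescue libraries of both cultures, and 1443 genes were called the same way in all 4 comparisons with control, against 189.4 for independent lists. Within a culture these comparisons share their control libraries. With those split, so that each served in a single comparison of its culture, 953 to 986 genes were called the same way in all 4, against 74.8 to 84.6 for independent lists. Changes that ZMYND8 made and its return did not undo would give the same count. Control and knockout labels exchanged in both cultures, which was left open above, could also give such a count. These explanations cannot be told apart from a single knockout group and a single rescue group per culture. How many separate lines stand behind each group is not known here.

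Of the 52 genes named for the knockout and tested, limma's test of the difference between cultures passed for 39, at adjusted p values from 5.9e-07 to 0.05. These genes were chosen mostly for changes within a culture, which favours a difference, and over all 14270 genes 4535 (31.8%) passed. The values that follow are the knockout change in mammospheres minus that in monolayer (log2). Among sterol and lipid genes, CYP27A1 differed by 0.56, MVD by 0.37, FASN by 0.39, ME1 by -0.29 and NPC1 by 0.69. Among cytokines, IL1B differed by 1.63 and CSF2 by 2.46. Among genes of cell division, TOP2A differed by -0.65, RRM2 by -1.32, MKI67 by -1.18 and PCNA by -0.84, and among chromatin partners HDAC1 by -0.61 and CHD4 by -0.31. The interferon genes OAS1 and OAS2 differed by 1.92 and 0.76. Among other genes, COL6A2 differed by 1.92, MMP2 by -0.90, MMP9 by 2.68, TGFBI by 1.2, SPARC by 0.92, GPR110 by -0.80, KISS1 by 2.28, ALOX5AP by 1.92 and MYH10 by -1. For GPR110 the sign comes from the pseudocount of 1, against control means of 0.472 TPM in mammospheres and 2.36 in monolayer. Its group means rose 31.7-fold in mammospheres and 26.3-fold in monolayer. The pseudocount also affects the size for other genes with a group mean of a few TPM or less, such as SPARC, COL6A2 and MMP2. The epithelial genes CLDN4, EPCAM and ELF3 differed by -0.84, -0.71 and 1.61. Another 11 of the 39 genes lay under 3 reads per library in at least 1 of the 4 groups, so that their fitted values depend on the pseudocount and do not give the size of a difference in the knockout effect. These were ABCG1 (1.34) and CCL2 (3.84), which lay under that floor in both mammosphere groups, and TFF1 (4.42), TFF2 (3.58), TFF3 (2.13), TMPRSS3 (4.69), EEF1A2 (1.62), LGR5 (1.66), CDH1 (1.08), SIGLEC15 (0.78) and MT1A (-1.51).

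Of 19 lists tested with camera for the same difference, 11 passed. Inflammatory cytokines differed by a median of 1.56 (adjusted p = 5.07e-12; adjusted p = 0.0392 with an estimated correlation) and by 1.5 without genes under the floor (adjusted p = 0.0512 with an estimated correlation), and cell division by -0.71 (adjusted p = 1.18e-14; adjusted p = 0.0936 with an estimated correlation). With an adjusted p of 0.0936 under an estimated correlation, sterol sensing differed by 0.15, LXR targets by 0.33, interferon stimulated genes by 0.39, mesenchymal markers by 0.49, endothelial and fibroblast markers by 1.02 and luminal markers by 0.22. Amino acid and ER stress genes differed by 0.09 and NRF2 targets by -0.24 (adjusted p = 0.107 with an estimated correlation for each), and ZMYND8 partners by -0.22 (adjusted p = 0.166 with an estimated correlation). Without genes under the floor, luminal markers differed by 0.16 and no longer passed (camera adjusted p = 0.285). NRF2 targets, which lost no gene there, did not pass either (camera adjusted p = 0.0532). Endothelial and fibroblast markers were not tested without such genes, so their 1.02 may rest on genes under the floor.

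Of the 59 genes named for rescue and tested, 50 passed limma's test that the change from knockout to rescue differed between cultures, at adjusted p values from 1.43e-09 to 0.0047. The choice of genes again favours a difference, and over all genes 8120 (56.9%) passed. The values that follow are mammospheres minus monolayer (log2). Among cholesterol enzymes, HMGCS1 differed by 2.07, IDI1 by 1.77, FDFT1 by 2.01, SQLE by 1.49, LSS by 1.31, TM7SF2 by 2.95, MSMO1 by 2.45 and SC5DL by 1.22. SREBF2 differed by 1.26, INSIG1 by 2.29, CYP27A1 by 1.17, NR1H3 by 1.69 and ABCA1 by -0.87. Among fatty acid genes, ACSS2 differed by 2.72, FASN by 1.82, FADS2 by 1.81 and SCD by 2.02. The hypoxia gene NDRG1 differed by 2.63, and the stress genes CHAC1, TRIB3, PSAT1 and DDIT3 by -1.84, -0.76, -1.56 and -1.10. The immune genes MX1, OAS3, IL6 and IL1A differed by -2.03, -2.25, -3.15 and -1.63.

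With rescue, OLFML3, CAPN8, TGFBI and SPARC differed between cultures by 4.15, 4.62, 0.72 and 2.63. MMP1 differed by -1.38, SUSD2 by -1.08, S100P by -2.79 and ASS1 by -2.34. GFPT2 differed by 1.23, ABCC2 by 1.77, and DMBT1 by 1.51, and ALOX5AP by -4.16, CSF1R by -1.34, SIGLEC15 by -1.12 and KISS1 by -1.73. The cell division genes TYMS and AURKB differed by -0.77 and -0.50. Here too the pseudocount affects the size for genes with a group mean of a few TPM or less, such as CAPN8 and SUSD2. Another 7 genes lay under the floor in at least 1 of the 4 groups, and their fitted values likewise give no size of a difference: TFF3 (2.54), TFF2 (0.72), SPINK1 (-1.62), GPR110 (2.51), SLPI (-1.94), CA9 (3.96) and CD96 (2.30). Besides cholesterol biosynthesis, 8 lists passed camera for this difference. Fatty acid synthesis differed by a median of 0.80, hypoxia by 0.77 and amino acid and ER stress genes by -1.06, and these 3 held with an estimated correlation (adjusted p = 0.0464, 0.0461 and 0.0461). Sterol sensing differed by 0.68 (adjusted p = 0.0770 with an estimated correlation), oxysterol enzymes by 0.83 (adjusted p = 0.0730 with an estimated correlation), LXR targets by 0.65 and interferon stimulated genes by -0.77 (adjusted p = 0.0801 with an estimated correlation for each), and cytokines by -1.29 (adjusted p = 0.0710 with an estimated correlation).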

How the results depend on the processing

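The voom fit on recovered reads, the splits of shared libraries, the list tests without genes under 3 reads per library and the difference of the rescue effect between cultures were chosen after the data were examined, and the other alternatives before. Under pseudocounts of 0.1 and 0.5, no filter on low values, median-of-ratios scaling, no variance trend, a replicate block, fits on the libraries of a comparison alone and voom, each count of calls stayed within 1.5 times its value, where the fits on the libraries of a comparison alone were not run for the knockout and rescue differences between cultures. Mammosphere knockout calls ranged from 7105 to 7643, monolayer knockout calls from 5826 to 7087, and monolayer rescue calls from 8822 to 9875.

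A required log2 change of at least 1 lowered each count by its own construction. It left 772 genes for the knockout in mammospheres and 881 in monolayer, 971 and 1932 for rescue against knockout, 1593 and 2205 for rescue against control, 2203 for the cultures, 517 for the knockout difference between cultures and 2119 for the rescue difference. Shared knockout calls numbered 378, and reversed calls 198 in mammospheres and 315 in monolayer.

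The number of lists called depended on the setting of camera and on the test. An estimated correlation also lowers camera's degrees of freedom, so lost calls need not be due to correlated genes alone. With an estimated correlation, list calls went from 8 to 0 for the knockout in mammospheres, 10 to 2 in monolayer, 8 to 0 for rescue in mammospheres, 13 to 2 in monolayer, 2 to 0 for rescue against control in mammospheres, 13 to 5 in monolayer, 11 to 1 for the knockout difference and 9 to 3 for the rescue difference. By fry, which asks another question, 16, 17 and 17 lists passed for the knockout in mammospheres, the knockout in monolayer and rescue in mammospheres, 18 for rescue against control in mammospheres, 17 for the cultures and 18 for the rescue difference. Without genes under 3 reads per library in a group, list calls went from 11 to 8 for the knockout difference and from 9 to 10 for the rescue difference. For the knockout difference, luminal markers and NRF2 targets no longer passed, and endothelial and fibroblast markers were not tested in that setting.

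With 1 library left out, its lone partner is assumed to vary like the other groups. Calls reversed by rescue in mammospheres ranged from 1740 (without mammosphere knockout replicate 1) to 2277, and the cause was not tested. Of the named genes, 3 changed sign in comparisons where they were not called, and the cause was not tested. SREBF2 with the knockout in mammospheres ranged from -0.02 to 0.054 and was -0.004 without mammosphere knockout replicate 1. CYP27A1 with the knockout in monolayer ranged from -0.25 to 0.017. ABCG1, near the floor, ranged from -0.125 to 0.034 with the knockout in mammospheres, from -0.068 to 0 with rescue in mammospheres and from -0.065 to 0.057 with rescue in monolayer. Over all named genes and left-out libraries, 1864 results kept their side of the threshold, 53 lost a call, 1 gained one and 6 changed sign. Under the alternatives that kept all libraries, at most 7 results for named genes lost a call and 0 changed sign.

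The replicate numbers showed no pairing across groups, and the replicate block gave 7174 and 6608 knockout calls in mammospheres and monolayer, 7947 and 9369 rescue calls, 9591 for the cultures, 3569 shared knockout calls and 2586 and 3031 reversed calls. Depth limits genes such as CYP7B1, whose 0 to 3 reads per library allow no test.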

Other observations

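The comparison of culture effects in knockout and rescue cells was chosen only after the data were examined, while both hypotheses and their tests in control cells were set down before the values of their genes were seen. The camera p values in this part are not adjusted over the lists.

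The cystatin genes differed between the control, knockout and rescue labels as well as between cultures. From knockout to rescue they fell in monolayer and rose in mammospheres. CST1, an inhibitor of secreted cysteine proteases, stood at 8060 ± 250 TPM in monolayer control, 1370 ± 73 in knockout and 211 ± 9.5 in rescue libraries, and at 58.3 ± 1.0, 43.8 ± 3.6 and 163 ± 12 in mammospheres. CST4 stood at 2900 ± 90, 329 ± 5.1 and 68.1 ± 1.6 TPM in monolayer, and at 60.1 ± 0.059, 21.9 ± 5.8 and 78.4 ± 4.7 in mammospheres. These genes belong to a family of similar copies, and their single values are uncertain for that reason. ALOX15B, a lipoxygenase, was at 0.145 ± 0.038, 0.25 ± 0.011 and 0.154 ± 0.044 TPM in the monolayer groups and at 44.9 ± 2.8, 45.0 ± 0.97 and 142 ± 8.6 in mammospheres. ANGPTL4, a regulator of lipid uptake, was highest in knockout cells of both cultures, at 94.9 ± 4.3 against 38.0 ± 2.1 TPM in monolayer control and 594 ± 16 against 273 ± 8.8 in mammosphere control.

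A first hypothesis held that glucocorticoid receptor targets are higher in mammospheres, since FKBP5 and RGS2, both known targets, were among the largest rises. FKBP5 stood at 6.69 ± 0.59, 5.36 ± 0.036 and 6.45 ± 0.068 TPM in the monolayer groups and at 164 ± 5.4, 125 ± 3.1 and 204 ± 7.1 in mammospheres. In 15 other targets the median change in control cells was 0.48, with 8 higher and 4 lower, and camera gave p = 0.0593, or p = 0.156 with an estimated correlation, so the test in control cells did not pass. In knockout cells the median was 0.87 (camera p = 0.000144, p = 0.017 with an estimated correlation) and in rescue cells 1.34 (p = 0.000695, p = 0.0267 with an estimated correlation). The labels do not list the additives of the mammosphere medium, so a steroid in it may or may not be the source.

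The other hypothesis held that targets of YAP and TEAD, which respond to attachment and spreading, are lower in mammospheres. In control cells 13 of 15 were lower and 0 higher, with a median of -0.86 (camera p = 1.17e-06, p = 0.00203 with an estimated correlation). In knockout cells 13 were lower with a median of -1.08 (p = 0.00202 with an estimated correlation), and in rescue cells 15 with a median of -1.50 (p = 0.000581 with an estimated correlation). Lower YAP activity in floating spheres is a candidate explanation, but serum and medium changed with attachment, and the test cannot separate them.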
